A study of Homo sapiens with 12 samples.

How the data were processed

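RNA was measured in 12 libraries of 2 human cell lines, 3 each of epidermal control, epidermal knockout, airway control and airway knockout, where the knockout is of TMPRSS4 and all cells were stimulated. Values are the deposited gene counts, whole numbers for 60483 Ensembl gene identifiers. The submitters' processing notes name hg38, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR; which tool made the counts, the annotation and the strand setting are not given in the sources used here. The label on extraction describes small RNA from another cell type, while 98.5% of the counts lay on protein-coding genes, and a tag for airway cells appears on the epidermal libraries too; groups were taken from the sample titles and treatments. Of counts from 1 to 20, 67.3 to 76.1% were even, so that read mates may have been counted separately, and an alternative halved the counts.

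Depth was 32924121 to 35439233 counts per library, the 10 highest genes held 3.80 to 4.85% of them, and the biological coefficient of variation was 0.0531 in epidermal and 0.0417 in airway cells. The floor was set at 3 counts per library. Identifiers were matched with their version removed to a table of gene names and to GENCODE release 29 on GRCh38, which gave the coordinates; 3730 identifiers without a symbol held 0.034% of counts. Of 164 named genes, 27 overlap a coding gene on the other strand and 10 on the same strand, and with the strand setting unknown their counts are uncertain to that extent.

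Each line was fitted alone in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test of knockout against control; the difference between lines was the interaction in a fit of all 12 libraries. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The 29 gene lists were fixed beforehand and those with at least 5 tested members were tested by camera of limma 3.58.1 with a preset correlation of 0.01 and a prior count of 2; camera with an estimated correlation and fry were run beside it. Calls were also counted with adjustment over each list alone. Genes called in both lines were compared with Fisher's exact test, and fold changes by Pearson and Spearman correlation. TMPRSS4 was also tested by exact permutation of its CPM values. Identity was described with 7 lists of cell type markers.

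The groups, comparisons, gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule named TMPRSS4; per line the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and all 3 knockouts on the same side of all 3 controls; per list and line up to 4 called members with the smallest adjusted p, with other members as examples; up to 8 genes per direction called the same way in both lines and 6 per direction called in opposite ways; the 5 largest differences per sign in the interaction with at least 5 CPM; and the 3 highest markers per line. A few genes that the rule named are not reported here; counts and lists include them. CDH1, EPCAM and COL1A1 in the airway line and the counts of KRT5 and VIM in the line that does not express them were chosen after their values were seen.

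Carry-over was measured after the data were seen, as the median percent of the other line's count. It used genes with a mean of at least 1000 counts in 1 line and at most 0.2% of that in their lowest library of the other. Choosing genes by their lowest library can favour genes that differ between libraries. Libraries above 0.15% were called high. The alternative settings chosen beforehand were DESeq2 1.42.0 with its Wald test or its size factors, no filter, a filter of 5 CPM in 3 libraries, a log2 fold change of at least 1, a joint fit, replicate number as a block, a prior count of 0.5 for lists, and each library left out. Added after the data were seen were the carry-over level as a covariate, high carry-over libraries only, genes with at least 5% expected carry-over left out and counts halved. Where libraries were left out the filter was rerun on those kept, so genes tested and list members could differ. Expected carry-over of a gene was taken at the highest percent of any library in the line. Up to 100 of the 200 splits over both lines (seed 11) and all 10 within a line were refitted. After its result was seen, the test of the carry-over level on genes called in opposite directions, first of kept signs alone, was widened to the counts in both directions, splits within a line were also refitted with the level, and the test of the level on the airway genes was set against the epidermal libraries.

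The fits were tested on simulated data with 200 changed genes. In the epidermal comparison edgeR recovered 51, 72 and 90% of genes changed 1.2-, 1.5- and 2-fold, with 6.42, 2.04 and 2.17% false among called genes. In the airway comparison it recovered 49.5, 79.5 and 90% (4.81, 3.05 and 4.76% false) and in the interaction 13, 73.5 and 74% (7.14, 2 and 5.73% false). A raised list was recovered by all 3 list methods with 0 other lists called. Genes were drawn independently of each other there, so the simulation does not show how often correlation between genes gives false list calls. The mitochondrial list had 0 tested genes, since mitochondrial counts were 0 in every library, and was left out. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made tables and figures.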

Results

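Gene expression was measured by sequencing in 2 human cell lines in which TMPRSS4, a type II transmembrane serine protease, had been knocked out, and in their control cells. Per the labels, the epidermal line (immortalized human epidermal cells) was treated with the cytokines TNFα and IFNγ, and the airway line (human airway epithelial cells) with house dust mite, a common inhaled allergen. The design gave 4 groups of 3 libraries: epidermal control, epidermal knockout, airway control and airway knockout. All 12 libraries came from stimulated cells, so each comparison set knockout against control under 1 stimulus. The series title names TMPRSS4 as a biomarker shared by asthma and atopic dermatitis, and the comparisons ask which transcripts differ with TMPRSS4 knockout in a model of each disease and which differ in both. Libraries held 32924121 to 35439233 counts, and 23048 to 23435 genes had at least 1 count. Whether replicates were separate cultures is not stated in the labels, so p-values measure only the spread between these libraries, which may be technical. The knockout method and the number of clones are not stated either. In both lines, differences between knockout and control cells unrelated to TMPRSS4 thus cannot be told apart from effects of the knockout.

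TMPRSS4 (ENSG00000137648.15) lies on the forward strand of chromosome 11, 118077012 to 118121890, in GRCh38. In epidermal controls 1, 2 and 3 it had 1179, 1067 and 1149 counts, which is 34.4, 31.3 and 33.5 CPM, the counts scaled to a common library size. In epidermal knockouts 1, 2 and 3 it had 506, 423 and 399 counts, which is 14.7, 12.4 and 11.5 CPM. The means were 33.1 ± 1.58 CPM in controls and 12.9 ± 1.62 CPM in knockouts (SD, n = 3 per group), so that 38.9% of the control level remained. TMPRSS4 fell by 1.36 ± 0.08 on the log2 scale (SE; adjusted p = 4.3e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 knockouts lay below all 3 controls. Within the high carry-over level described next the TMPRSS4 level changed by -1.17 (log2), and with 1 library left out it ran from -1.47 to -1.29. The exact two-sided permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. In the airway line TMPRSS4 was near the detection floor in both groups. Airway controls 1, 2 and 3 had 0, 0 and 4 counts and airway knockouts 1, 2 and 3 had 0, 4 and 4, where 3 counts correspond to 0.0847 to 0.0911 CPM in these libraries. No fold change is given for the airway line, and a fall of TMPRSS4 was not detectable at this depth. The labels do not say which part of the gene was altered, and counts over the whole gene can include transcripts that make no protein. TMPRSS4 overlaps SMIM35 on the other strand, and without a stated strand setting reads of the pair cannot be told apart. Floors and intervals here cover counting error only.

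**Figure D1:**
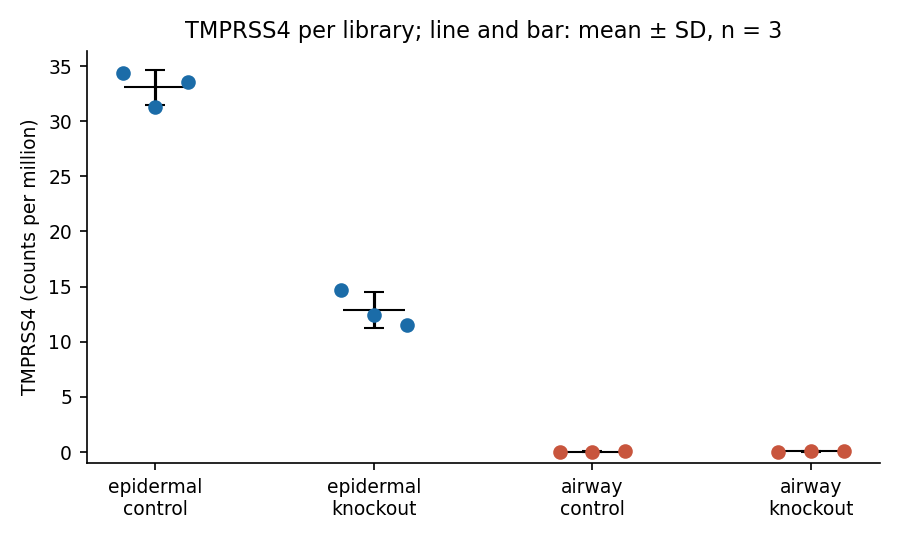
TMPRSS4 in CPM (vertical axis) in each of the 12 libraries, by group; points are libraries, and the line and bar are the mean and SD of 3. Epidermal controls lie between 31.3 and 34.4 CPM, epidermal knockouts between 11.5 and 14.7 CPM, and the airway libraries at or near 0.

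Marker genes described the identity of the lines. The epidermal libraries expressed the basal keratins KRT14 (2344 ± 136 CPM, SD over 6 libraries) and KRT5 (1526 ± 19.7 CPM), the hemidesmosomal collagen COL17A1 (1369 ± 58.4 CPM) and the simple-epithelial keratin KRT8 (1945 ± 67.5 CPM). KRT14 fell in epidermal knockouts (log2 fold change -0.15, adjusted p = 0.0024), while KRT5 (-0.02, adjusted p = 0.83) was not called, a call being an adjusted p under 0.05. KRT19 (634 ± 25.5 CPM) and CDH1 (584 ± 13.4 CPM), genes of epithelial cells, were also expressed there. The airway libraries expressed the intermediate filament VIM (942 ± 22.8 CPM), KRT8 (612 ± 21.9 CPM), KRT7 (283 ± 8.93 CPM) and KRT18 (169.8 ± 3.93 CPM) with the surface protein THY1 (178 ± 14.3 CPM), SFN (114 ± 4.90 CPM) and KRT10 (32.2 ± 1.32 CPM). VIM, THY1 and PDGFRB (44.4 CPM) were the 3 highest members of the fibroblast marker list there, but only 5 of its 14 members averaged at least 1 CPM. CDH1 averaged 0.991 CPM and EPCAM 1.42 CPM, and whether the line is as labelled was not tested. As CDH1 was high in the epidermal line, carry-over between the lines, described next, can add to its airway value. In airway knockouts KRT8 rose (0.08, adjusted p = 0.029), THY1 fell (-0.20, adjusted p = 6.7e-04) and PDGFRB, a growth factor receptor, rose (0.40, adjusted p = 1.9e-04). Markers of ciliated cells, endothelium, leukocytes and melanocytes were low, and the highest means were 6.19 CPM for DNAH5 and 7.57 CPM for MITF in the epidermal line and 12.3 CPM for MITF and 4.68 CPM for CD14 in the airway line. In CPM, the other leading markers of these types and of fibroblasts were COL1A1 (10.2), S100A4 (5.16), VIM (2.18), ERG (1.896), PMEL (1.63), CAPS (1.499), ITGAM (1.44), CCDC78 (1.04), CD14 (0.806), PTPRC (0.510), VWF (0.446), MLANA (0.335) and CDH5 (0.321) in the epidermal line and COL1A1 (17.0), CAPS (2.04), DNAH5 (1.96), CCDC78 (1.14), CDH5 (1.08), VWF (1.03), TYRP1 (0.867), PMEL (0.690), PTPRC (0.516) and LYZ (0.361) in the airway line. TIE1, an endothelial receptor kinase, fell in airway knockouts from 2.03 to 0.387 CPM (-2.38, adjusted p = 2.7e-05).

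Each library also held traces of genes that belong to the other line. Over 42 genes of the airway line, epidermal libraries carried a median of 0.0864 to 0.309% of the airway count, and over 82 genes of the epidermal line, airway libraries carried 0.0746 to 0.293% of the epidermal count. The traces had 2 levels. They were high, 0.182 to 0.309%, in the 3 epidermal controls, epidermal knockout 1, airway control 3 and the 3 airway knockouts, and low, 0.0746 to 0.127%, in epidermal knockouts 2 and 3 and airway controls 1 and 2. KRT5 had 30 and 27 counts in airway controls 1 and 2 against 133 in airway control 3 and 129, 73 and 119 in the airway knockouts. VIM had 47 and 32 counts in epidermal knockouts 2 and 3 against 83 in epidermal knockout 1. The low level held knockouts only in the epidermal line and controls only in the airway line, so the comparisons are also given within the high level, which sets epidermal knockout 1 against 3 controls and 3 airway knockouts against airway control 3. The single library is there assumed to vary like the others, and a fit with the level as a covariate rests on the same 2 single libraries. For epidermal knockout 1 that assumption is doubtful. The mean chi-square per gene, which grows as 2 replicates differ, was 9.25 against knockout 2 and 5.15 against knockout 3. It was 4.19 between knockouts 2 and 3 and 3.20 to 3.69 between epidermal controls. Results within the high level in epidermal cells thus rest on the knockout library least like the other 2.

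**Figure D2:**
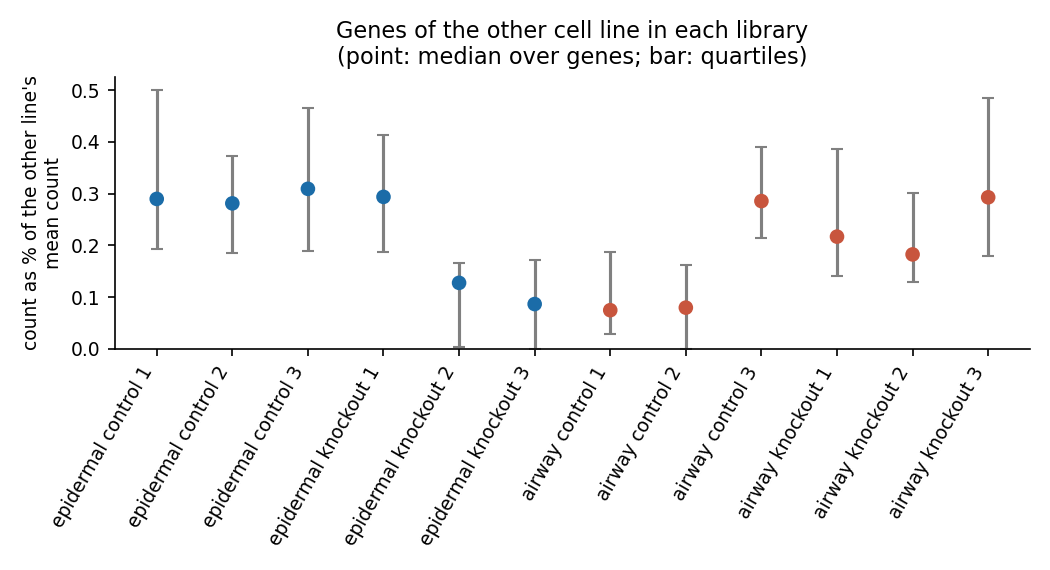
Median count of the other line's genes in each library, as a percent of their mean count in that line (vertical axis), over 42 genes in epidermal and 82 genes in airway libraries; bars are quartiles over genes. Epidermal knockouts 2 and 3 and airway controls 1 and 2 lie between 0.0746 and 0.127% and the other 8 libraries between 0.182 and 0.309%.

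The first comparison asks what TMPRSS4 knockout changes in epidermal cells under TNFα and IFNγ. The basement membrane genes LAMB3 and NID1 fell in knockout cells, while the collagen IV chain COL4A4 rose (log2 fold change 0.45). Of 28 type I interferon-stimulated genes 12 fell (list adjusted p = 3.6e-11 by camera, 0.095 with an estimated correlation). Filaggrin (FLG), the barrier protein of the outer epidermis, rose from 35.1 ± 2.26 to 46.8 ± 3.14 CPM. RSAD2, which encodes the antiviral protein viperin, fell from 217 ± 1.65 to 149.8 ± 6.56 CPM (mean ± SD, n = 3 per group), and LCN2, an antimicrobial iron-binding protein, fell from 18.2 ± 0.839 to 12.5 ± 0.555 CPM. IL1RL1, the receptor of the alarmin IL-33, fell from 17.3 ± 0.682 to 11.8 ± 0.939 CPM, and PTGS2, the inducible cyclooxygenase, from 39.5 ± 0.627 to 27.0 ± 2.68 CPM. Most changes were small, with a median size of 0.30 on the log2 scale among called genes.

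Of 16190 genes tested, 207 were called at an adjusted p under 0.05 (66 higher and 141 lower in knockouts) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 19 changed at least 2-fold (3 higher and 16 lower). The count varied with the libraries kept. It was 55, 48 and 60 without epidermal control 1, 2 or 3. Without epidermal knockout 1, 2 or 3 it was 601, 224 and 59. Within the high carry-over level 325 genes were called (183 higher and 142 lower), of which 101 were among the 207. The same count was 464 with no filter on low counts and 341 with all 12 libraries in a joint fit.

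Among called genes with at least 5 CPM, the largest rises were those of ANKRD1, a mechanically regulated nuclear protein (log2 fold change 0.61 ± 0.12, SE, adjusted p = 0.021), the RNA polymerase I subunit POLR1G (0.55 ± 0.09, 0.0074), the Nogo receptor relative RTN4RL1 (0.54 ± 0.08, 0.003) and the transcription factor TCF7L1 (0.52 ± 0.10, 0.015). They were followed by the actin-binding AIF1L (0.50), the collagen IV chain COL4A4 (0.45), the ligand WNT4 (0.43), FLG (0.42), the receptor LRP4 (0.39) and DKK1, a secreted inhibitor of WNT signalling (0.38). After TMPRSS4 itself, the largest falls were those of PDZK1IP1, a small membrane protein (-1.01 ± 0.11, adjusted p = 1.9e-04), the translation elongation factor EEF1A2 (-0.81 ± 0.08, 3.7e-05), the cytoskeletal adaptor DTNA (-0.70 ± 0.12, 0.0093) and the ETS-family transcription factor FLI1 (-0.69 ± 0.09, 7.1e-04). KRT81, a hair keratin (-0.67), the basement membrane linker NID1 (-0.58), SNPH (-0.56), IL1RL1 (-0.55) and PTGS2 (-0.55) completed the 10 largest falls. In each of these 20 genes all 3 knockouts lay on the same side of all 3 controls, as the rule for naming required. COL4A4, PDZK1IP1, EEF1A2, FLI1, NID1, IL1RL1 and PTGS2 passed the test with any 1 of the 6 libraries left out. ANKRD1, POLR1G, RTN4RL1, TCF7L1, AIF1L, WNT4, LRP4, DTNA and KRT81 were not called within the high carry-over level, with adjusted p from 0.071 (RTN4RL1) to 0.26 (TCF7L1) and the same signs.

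Type I interferon-stimulated genes, which encode antiviral proteins, fell as a group in epidermal knockouts. Of 28 tested, 12 fell and 0 rose, with a mean log2 fold change of -0.14 (limma's camera with a preset correlation, adjusted p = 3.6e-11; adjusted p = 0.095 with an estimated correlation); adjusted over the list alone, 17 fell. RSAD2 (-0.54 ± 0.04, adjusted p = 1.4e-06), the OAS-like protein OASL (-0.34 ± 0.03, 2.5e-05), the helicase DDX60 (-0.32 ± 0.03, 1.3e-04) and the RNA-binding IFIT1 (-0.29 ± 0.03, 1.9e-04) were called with any 1 library left out and within the high carry-over level. The interferon-gamma response list was called as lower (mean -0.07; 4 of 20 fell, 0 rose, 5 fell adjusted over the list alone; adjusted p = 0.0082; adjusted p = 0.22 with an estimated correlation), with falls of the tRNA synthetase WARS1 (-0.17), the apolipoprotein APOL1 (-0.29), the T cell chemoattractant CXCL11 (-0.34) and the guanylate-binding GBP4 (-0.26). The MHC class I presentation list also fell (mean -0.06; 2 of 17 fell, 0 rose, 4 fell adjusted over the list alone; adjusted p = 0.016; adjusted p = 0.22 with an estimated correlation), led by HLA-B (-0.19), whose reads can be shared with similar genes. The interferon-gamma call was lost without epidermal control 1 or knockout 2, and the MHC class I call without epidermal control 3 or knockout 1 or 3, at adjusted p of up to 0.24 and 0.064. The interferon-gamma mean was itself positive without epidermal control 1 (0.06), control 2 (0.01), control 3 (0.01) or knockout 2 (0.06). Those fits reran the filter and tested 16552 to 16652 genes against 16190, so members of the list could change. On the same members the means without control 1, 2 or 3 would average close to -0.07. These signs are thus not read as effects of the single libraries left out. The type I list was called within the high carry-over level (adjusted p = 1.8e-06) and the interferon-gamma list, whose mean was there positive (0.09), and the MHC class I list were not (adjusted p = 0.28 and 0.1). MHC class II genes (mean -0.11, adjusted p = 0.13), NF-kB and TNF targets (-0.02, 0.13), inflammatory cytokines and chemokines (-0.07, 0.39) and type 2 and alarmin genes (-0.14, 0.054) were not called as lists. Among their members the complement protein C3 (-0.19), the cytokine IL24 (-0.45), the chemokine CCL5 (-0.17) and IL1RL1 fell.

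Extracellular matrix genes fell as a group in epidermal knockouts, with LAMB3 and NID1 among them. Of 26 tested, 5 fell and 2 rose (mean -0.14, adjusted p = 1.4e-05; adjusted p = 0.095 with an estimated correlation; adjusted over the list alone, 12 fell and 2 rose). LAMB3 (-0.17 ± 0.03, adjusted p = 0.0031), a laminin chain that anchors basal keratinocytes, and NID1 (-0.58 ± 0.07, 5.9e-04) kept their calls with any 1 library left out, and the fibrillin FBN2 (-0.27) fell as well. ITGA5, the fibronectin receptor subunit, fell (-0.23 ± 0.03, 0.0025) in the mesenchymal transition list, which was not called (mean -0.08, median 0.01, adjusted p = 0.39). Of the cell junction list, claudin CLDN1 rose (0.17) and the desmosomal cadherin DSG2 fell (-0.11), and the list was not called (mean -0.02, adjusted p = 0.23). Matrix proteases were not called as a list (mean -0.0032, median 0.03, adjusted p = 0.73), with 0 members called over all genes and 2 higher and 4 lower adjusted over the list alone. Membrane serine proteases and their inhibitors, the family of TMPRSS4, were not called either (mean 0.01, median -0.02, adjusted p = 0.4), with 0 members called over all genes or over the list alone.

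In the differentiation and barrier list FLG rose (0.42 ± 0.06, adjusted p = 0.0031), a call lost without epidermal control 2 (0.054) and in the joint fit (0.066), and the suprabasal keratin KRT1 rose from 0.146 ± 0.0770 to 0.679 ± 0.0884 CPM (2.19 ± 0.48, 0.035), a call that was lost in 5 of the 6 fits with 1 library left out. The list itself was not called (mean 0.12, 2 of 18 higher, also adjusted over the list alone, adjusted p = 0.13). In the hyperproliferative and antimicrobial list LCN2 (-0.55 ± 0.08, 0.002), the calprotectin subunit S100A9 (-0.36) and the stress keratin KRT17 (-0.17) fell, and the list was not called (mean -0.06, adjusted p = 0.14). The S100A9 call was lost without epidermal control 1, 2 or 3 (edgeR adjusted p of up to 0.18) and in the joint fit. In the mucus and airway secretory list the chloride channel CFTR (-1.01), the cell-surface mucin MUC16 (-0.36) and AGR2 (-1.04), a disulfide isomerase of mucin-making cells, fell, and the list was not called (mean -0.06, 3 of 7 lower, adjusted p = 0.14).

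Of the unfolded protein and amino acid stress list, 4 of 22 genes fell and 0 rose in epidermal knockouts. HSP90B1 (-0.23 ± 0.02, adjusted p = 2.5e-05), HSPA5, known as BiP (-0.18 ± 0.02, 3.7e-04), the disulfide isomerase PDIA4 (-0.23 ± 0.03, 5.6e-04) and HERPUD1 (-0.31 ± 0.04, 5.6e-04) were called with any 1 library left out. The list was called (mean -0.09; 5 lower adjusted over the list alone; adjusted p = 5.8e-04; adjusted p = 0.22 with an estimated correlation). The mitosis list fell (mean -0.08; adjusted p = 1.4e-05; adjusted p = 0.26 with an estimated correlation), with only the kinesin KIF20A called over all genes (-0.22) and 10 of 26 lower adjusted over the list alone. DNA replication genes (mean 0.05; adjusted p = 0.018; adjusted p = 0.36 with an estimated correlation), Hippo pathway targets (0.10; adjusted p = 0.018; adjusted p = 0.22 with an estimated correlation) and cytosolic ribosomal proteins (0.04; adjusted p = 0.0018; adjusted p = 0.52 with an estimated correlation) were higher as lists. Their called members were the coagulation receptor F3 (0.17), ANKRD1 and RPL23 (0.13), and 0 replication genes were called alone by edgeR over all genes or over the list. The replication and ribosomal lists were not called by fry (adjusted p = 0.082 and 0.13). The replication call was lost without epidermal control 1 or 3 or knockout 2 (adjusted p of up to 0.12), and the Hippo call without epidermal knockout 1 or 3 (up to 0.054). The mitosis and unfolded protein lists were called within the high carry-over level (adjusted p = 0.0021 and 0.034), as was the matrix list (6.3e-04), and the replication, Hippo and ribosomal lists were not (0.36, 0.13 and 0.086). Lists of AP-1 genes (mean -0.01, median 0.03, adjusted p = 0.42), p53 targets (0.0029, median -0.02, 0.76), hypoxia genes (-0.01, 0.4), cholesterol synthesis (0.03, 0.14), NRF2 targets (-0.08, 0.5), TGF-beta and BMP targets (-0.03, 0.69), WNT genes (0.03, 0.14) and histones (-0.05, 0.69) were not called. Among their members the glycolytic enzyme ENO2 (-0.26), the ferritin chain FTL (-0.15) and haem oxygenase HMOX1 (-1.01) fell, and squalene epoxidase SQLE (0.15), DKK1 and WNT4 rose. In all, camera called 9 of 28 lists with the preset correlation, 0 with an estimated one, and fry called 8.

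Of the 72 results for named genes called in the epidermal line, 21 kept an adjusted p under 0.05 in each of the 6 fits with 1 library left out. Refits reuse libraries that chose these genes, so a kept sign in them is no separate support. Within the high carry-over level 41 of the 72 passed, and all 72 kept their sign.

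The next comparison asks what TMPRSS4 knockout changes in airway cells under house dust mite. MMP1, the interstitial collagenase, fell from 78.3 ± 1.78 to 19.0 ± 1.29 CPM in knockouts. FN1 (fibronectin) rose from 1938 ± 32.4 to 2635 ± 40.0 CPM and COL5A1, a collagen V chain, from 146 ± 5.61 to 232 ± 4.71 CPM. Of the cholesterol synthesis list 9 of 23 genes rose (list adjusted p = 1.1e-05; 0.13 with an estimated correlation), and of the unfolded protein and amino acid stress list 8 of 22 fell (0.0018; 0.31). Among cytokines, IL24 fell from 9.54 ± 0.344 to 3.91 ± 0.432 CPM and CCL5 rose from 25.7 to 32.5 CPM. TMPRSS4 itself was near the floor in these cells in both groups.

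In the airway line 1443 of 16261 genes were called (659 higher and 784 lower in knockouts), and 66 changed at least 2-fold (35 higher and 31 lower). The median size among called genes was 0.22 on the log2 scale. The count was 866 without airway control 1 and 954 without airway control 3. Within the high carry-over level, where a single control entered, 402 genes were called (192 higher and 210 lower), 377 of them among the 1443.

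Among called airway genes with at least 5 CPM and all 3 knockouts on the same side of all 3 controls, the largest rises were those of ACKR3, a scavenging chemokine receptor (log2 fold change 1.66 ± 0.12, SE, adjusted p = 5.0e-08), the calcium channel subunit CACNG4 (1.27 ± 0.09, 1.6e-08), the inhibitory SMAD6 (1.13 ± 0.11, 1.2e-06) and the immediate early factor EGR1 (0.98 ± 0.08, 1.7e-07). EEF1A2 (0.98), the adhesion scaffold NEDD9 (0.97), the cytolinker EPPK1 (0.93), the oxidised LDL receptor OLR1 (0.85), the matricellular THBS2 (0.84) and the complement protease C1S (0.84) followed. By the same rule the largest fall was that of MMP1 on chromosome 11, 102789920 to 102798160 (-2.04 ± 0.05, adjusted p = 1.6e-14), followed by IL24 (-1.29 ± 0.12, 7.7e-07), the lysosomal membrane protein LAMP3 (-1.21 ± 0.09, 7.9e-08) and the exchange factor DOCK4 (-1.01 ± 0.07, 2.2e-08). The GTPase regulator ARHGDIB (-0.84), the transmembrane collagen COL13A1 (-0.83), LPXN (-0.80), transglutaminase TGM2 (-0.77), the clock factor NPAS2 (-0.77) and INSYN2B (-0.75) fell as well. All 20 of these genes were called with any 1 of the 6 libraries left out, and 19 of them within the high carry-over level, the exception being C1S (0.63, adjusted p = 0.073).

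Extracellular matrix genes rose as a group in airway knockouts. Of 28 tested, 14 rose and 3 fell (mean 0.20, adjusted p = 5.4e-04; adjusted p = 0.31 with an estimated correlation; adjusted over the list alone, 15 rose and 3 fell). The collagen V chains COL5A1 (0.67 ± 0.03, adjusted p = 1.2e-10) and COL5A2 (0.57 ± 0.03, 9.1e-10), the fibrillin FBN1 (0.48 ± 0.03, 1.0e-09) and the proteoglycan HSPG2 (0.44 ± 0.03, 7.9e-08) led, and COL1A1 rose (0.50, adjusted p = 1.7e-04). Of the mesenchymal transition list 7 of 24 rose and 3 fell (8 and 7 adjusted over the list alone), including the matricellular SPARC (0.49 ± 0.02, 1.1e-11), FN1 (0.44 ± 0.02, 1.1e-11) and TGFBI (0.23 ± 0.02, 1.2e-06), which rose, and the hyaluronan receptor CD44 (-0.24 ± 0.02, 9.1e-07), which fell. That list was not called (mean 0.05, median -0.03, adjusted p = 0.84). Matrix proteases and their inhibitors fell (mean -0.15; 6 of 16 fell and 1 rose, 9 and 2 adjusted over the list alone; adjusted p = 0.0049; adjusted p = 0.23 with an estimated correlation). Beside MMP1 these included the nexin SERPINE2 (-0.29) and the activator PLAT (-0.22). Targets of TGF-beta and BMP rose (mean 0.22; 7 of 19 rose and 1 fell, 9 and 1 adjusted over the list alone; adjusted p = 5.4e-04; adjusted p = 0.15 with an estimated correlation), with SMAD6, TGFBI and the receptor TGFBR1 (0.26) higher. The protease and TGF-beta lists were called within the high carry-over level (adjusted p = 0.027 and 0.011) and the matrix list was not (mean 0.13, adjusted p = 0.075), while COL5A1 (0.61) and FN1 (0.43) were.

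Cholesterol synthesis genes rose in airway knockouts, 9 of 23 with 0 lower (13 higher and 1 lower adjusted over the list alone; mean 0.11; adjusted p = 1.1e-05; adjusted p = 0.13 with an estimated correlation). They included the synthase HMGCS1 (0.36 ± 0.03, adjusted p = 1.4e-07), the sterol sensor partner INSIG1 (0.32 ± 0.03, 3.4e-06) and the isomerase IDI1 (0.23 ± 0.04, 0.0013). Unfolded protein and amino acid stress genes fell, 8 of 22 with 0 higher (11 lower and 1 higher adjusted over the list alone; mean -0.08; adjusted p = 0.0018; adjusted p = 0.31 with an estimated correlation). HSPA5 (-0.15), the pseudokinase TRIB3 (-0.22), its regulator ATF4 (-0.17) and the serine synthesis enzyme PSAT1 (-0.16) were among them. AP-1 and immediate early genes fell as a list, 10 of 27 lower and 4 higher (14 and 6 adjusted over the list alone; mean -0.07; adjusted p = 0.011; adjusted p = 0.25 with an estimated correlation). The AP-1 subunit FOSL1 (-0.46 ± 0.03, 2.7e-09), PHLDA1 (-0.42) and the phosphatase DUSP4 (-0.31) fell, and EGR1 rose. Hippo pathway targets fell (mean -0.05; 5 of 19 lower and 1 higher, 8 and 1 adjusted over the list alone; adjusted p = 0.025; adjusted p = 0.25 with an estimated correlation), with F3 (-0.22), MYOF (-0.14) and ASAP1 (-0.16) lower and the ligand TGFB2 (0.23) higher. Ribosomal protein genes fell slightly (mean -0.06; 2 of 32 lower, 7 adjusted over the list alone; adjusted p = 0.0012; adjusted p = 0.68 with an estimated correlation), led by RPS3 (-0.15), whose reads can be shared with pseudogenes. The AP-1 call was lost without airway control 3 or knockout 2 (adjusted p of up to 0.069), the Hippo call without airway control 1 or 3 or knockout 1 (up to 0.065) and the ribosomal call without airway control 2 or knockout 1 (up to 0.074) and by fry (0.29), its mean running from -0.090 to -0.031 with 1 library left out. The cholesterol and unfolded protein lists were called within the high carry-over level (adjusted p = 0.0038 and 0.048), and the AP-1, Hippo and ribosomal lists were not (0.075, 0.075 and 0.29). The AP-1 mean was there positive (0.002).

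Type I interferon-stimulated genes were higher as a list in airway knockouts (mean 0.11; 6 of 28 rose and 1 fell, 9 and 1 adjusted over the list alone; adjusted p = 8.0e-04; adjusted p = 0.31 with an estimated correlation). OASL (0.34 ± 0.07, adjusted p = 0.0055), the ubiquitin-like ISG15 (0.23 ± 0.05, 0.0032) and IFIT2 (0.15 ± 0.03, 0.0027) rose and RSAD2 fell (-0.35 ± 0.05, 2.2e-04). The list was not called within the high carry-over level (mean 0.02, adjusted p = 0.52), and OASL (0.19, 0.3), ISG15 (0.20, 0.18) and IFIT2 (0.11, 0.27) were not either, while RSAD2 was (-0.35, 0.011). NF-kB and TNF targets were higher (mean 0.13; 3 of 18 rose, 9 rose and 2 fell adjusted over the list alone; adjusted p = 0.048; adjusted p = 0.55 with an estimated correlation), with TNFAIP2 (0.27), the mitochondrial dismutase SOD2 (0.23) and the adaptor TRAF1 (0.56). That call was lost without airway control 1 or 2 or knockout 1 or 3 (adjusted p of up to 0.19), by fry (0.064), with genes with carry-over left out (0.067) and within the high level (0.52). The interferon-gamma list (mean 0.03, adjusted p = 0.27) and the MHC class I list (0.05, 0.11) were not called. In them APOL1 (0.25), PARP14 (0.12) and HLA-B (0.14) rose and GBP5 (-0.68) and the peptidase ERAP2 (-0.09) fell. Of the cytokines, CCL5 (0.34) and LIF (0.30) rose and IL24 and IL11 (-0.35) fell. The cytokine list (mean -0.07, median 0.13, camera direction up, adjusted p = 0.63), MHC class II genes (0.07, 0.75) and type 2 and alarmin genes (-0.12, 0.21) were not called.

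Epithelial lists in the airway line held few expressed members and moved with the carry-over level. The differentiation and barrier list (mean 0.38, 6 tested, 1 higher, 2 adjusted over the list alone; adjusted p = 0.025; adjusted p = 0.25 with an estimated correlation) and the membrane serine protease list (0.42, 7 tested, 2 higher, also adjusted over the list alone; adjusted p = 0.048; adjusted p = 0.31 with an estimated correlation) were called as higher. Within the high level neither was (adjusted p = 0.52 and 0.49). The barrier call was lost without airway control 1 or 2 or knockout 2 (up to 0.12), and the serine protease call without airway control 1 or 2 or any 1 of the knockouts (up to 0.11). Transglutaminase TGM1 (0.50), the thrombin receptor F2R (0.21) and the sodium channel subunit SCNN1A (0.45) rose, and so did KRT17 (0.58 ± 0.03, adjusted p = 7.7e-10) and the mucin MUC1 (0.73 ± 0.09, 4.4e-05), both also within the high level. The hyperproliferative and mucus lists had 4 and 3 tested members and were not tested as lists. Of the junction genes JUP (0.27) rose and OCLN (-0.24) and PARD3 (-0.13), components of tight junctions and polarity, fell, and the list was not called (mean 0.27, adjusted p = 0.084).

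The mitosis, replication, hypoxia, NRF2, p53 and WNT lists were not called in the airway line. Mitotic KIF20A (0.15), CDK1 (0.16), KIF11 (0.09) and NUSAP1 (0.09) rose (list mean 0.01, adjusted p = 0.66), as did the replication genes MCM6 (0.18), RRM2 (0.11) and PCNA (0.12), while CHEK1 (-0.18) fell (list mean 0.03, 0.14). Of the hypoxia list the collagen hydroxylase P4HA2 (0.26) and PFKFB4 (0.31) rose and ANGPTL4 (-0.50) and ADM (-0.31) fell (list mean 0.06, 0.36). Of the NRF2 list ABCC3 (0.32) rose and TXNRD1 (-0.13) and SLC7A11 (-0.16) fell (list mean 0.07, 0.998). The p53 targets SESN2 (-0.28) and AEN (-0.19) fell (list mean 0.03, 0.66), as did DKK3 (-0.22) and SFRP1 (-0.27), secreted modulators of WNT signalling (list median -0.08, 0.76). Histones were not called (list mean 0.01, median -0.0045, 0.92). In all, camera called 12 of 26 lists with the preset correlation, 0 with an estimated one, and fry called 15. Of the 112 results for named genes called in the airway line, 90 kept their call with any 1 library left out. Here too refits reuse libraries that chose the genes, so a kept sign in them is no separate support. Within the high carry-over level 66 of them passed, and all kept their sign.

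**Figure D3:**
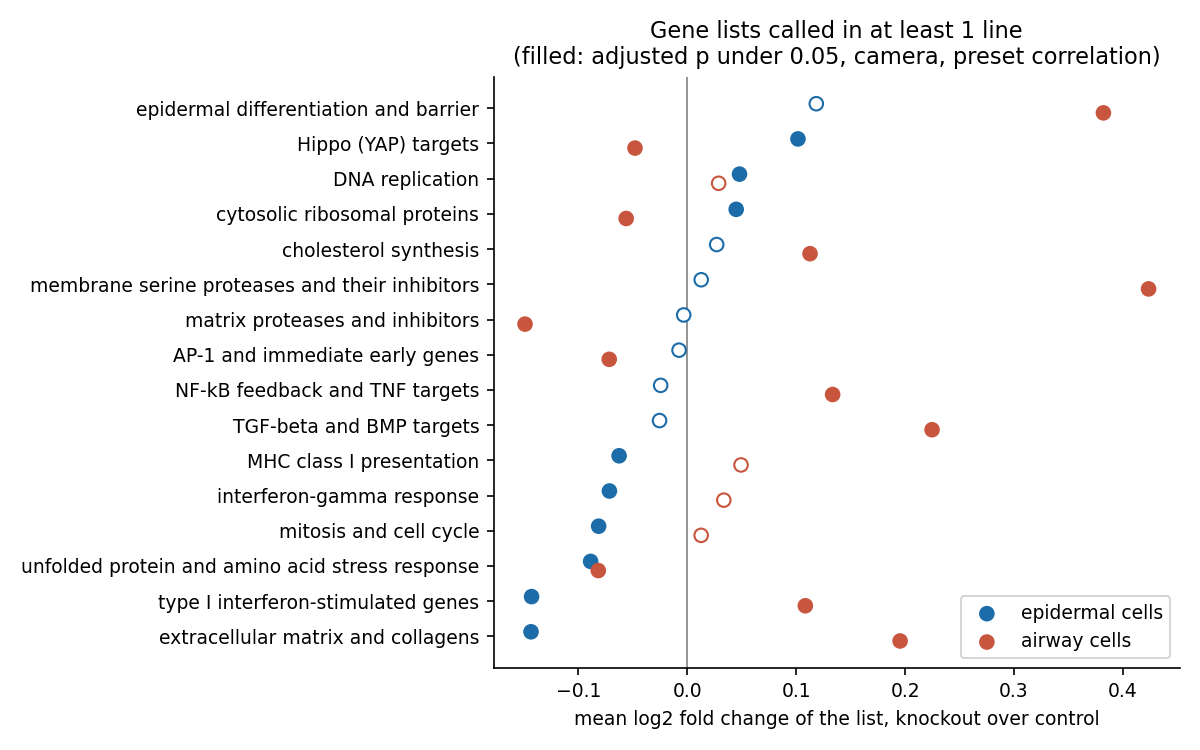
Mean log2 fold change of the tested members of each gene list, knockout over control (horizontal axis), in epidermal and airway cells, for lists called in at least 1 line; filled points have an adjusted p under 0.05 by camera with the preset correlation. The type I interferon list lies at -0.14 in epidermal and 0.11 in airway cells, and the extracellular matrix list at -0.14 and 0.20.

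The difference between the 2 knockout effects was tested directly, as an interaction over all 12 libraries. MMP1 fell in airway cells and was not called in epidermal cells (21.3 ± 2.17 and 21.7 ± 1.84 CPM), a difference of 2.06 on the log2 scale (epidermal minus airway, adjusted p = 5.1e-11). FAT3, a large cadherin, rose in epidermal cells from 1.09 ± 0.447 to 5.18 ± 0.218 CPM (2.24 ± 0.22, adjusted p = 3.7e-05) and had 10.9 ± 0.520 and 13.1 ± 0.159 CPM in airway cells (difference 1.96, 6.2e-06). COL27A1 (1.17, 1.1e-05), LAMP3 (1.08, 2.0e-04) and the metalloreductase STEAP1 (1.24, 0.0083) also had more positive effects in epidermal cells. STEAP1 was not called within the high level (0.85, 0.31). The most negative differences with at least 5 CPM over the 12 libraries came from genes that 1 line barely expressed. KLK5, an epidermal protease, and PPP1R14C had 0 counts in airway controls and 0.123 and 0.114 CPM in airway knockouts, COL22A1 had 0 and 0.132 CPM, and TMTC1 and ZYG11A had 0.136 and 0.175 CPM in epidermal controls and 0 in knockouts. None of these 5 was called within the high level, where adjusted p ran from 0.16 to 0.23, and for KLK5, PPP1R14C and TMTC1 the carry-over expected in that line exceeded the count. In all, 860 of 18091 genes were called (398 positive and 462 negative differences) and 91 differed at least 2-fold (26 and 65). The count was 554 without airway control 1, and within the high level 364 genes were called (201 and 163), 294 of them among the 860.

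Interferon and matrix genes had lower knockout effects in epidermal than in airway cells. The type I interferon list differed by a mean of -0.26 (13 of 28 lower and 0 higher, 18 lower adjusted over the list alone; adjusted p = 4.2e-12; adjusted p = 0.057 with an estimated correlation) and the matrix list by -0.33 (13 of 28 lower and 0 higher, 16 lower adjusted over the list alone; adjusted p = 6.5e-11; adjusted p = 0.057 with an estimated correlation). Lower effects in epidermal cells were also called for the MHC class I (-0.12; adjusted p = 0.057 with an estimated correlation), mitosis (-0.11; 0.18), TGF-beta (-0.22; 0.25), NF-kB (-0.22; 0.26), interferon-gamma (-0.16; 0.3), cell junction (-0.31; 0.36), cholesterol (-0.10; 0.33) and hyperproliferative keratinocyte lists (-0.50; 0.23). Higher effects were called for the Hippo (0.14; 0.18), ribosomal (0.09; 0.36) and AP-1 lists (-0.01; 0.18). For AP-1 the mean was negative while the median (0.06) and the test pointed up. Camera called 13 of 28 lists with the preset correlation, 0 with an estimated one, and fry called 17. The interferon-gamma list was called in 6 of the 12 fits with 1 library left out and the hyperproliferative list in 5, and the AP-1 call was lost without airway knockout 2 and the cholesterol call without epidermal control 3 (adjusted p of up to 0.13, 0.11, 0.056 and 0.060). Within the high level the type I interferon (mean -0.17), matrix (-0.22), MHC class I (-0.10), mitosis (-0.10), Hippo (0.17) and ribosomal (0.08) lists were called, and the interferon-gamma mean changed sign to 0.18 (adjusted p = 0.76). The means of the junction (-0.04, 0.46) and hyperproliferative lists (-0.05, 0.75) were there close to 0, and the NF-kB (0.14), TGF-beta (0.084), cholesterol (0.12) and AP-1 lists (0.087) were not called. The junction call was also lost with genes with carry-over left out (adjusted p = 0.34) and by fry (0.064), the AP-1 call with those genes left out (0.056) and the ribosomal call by fry (0.072).

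**Figure D4:**
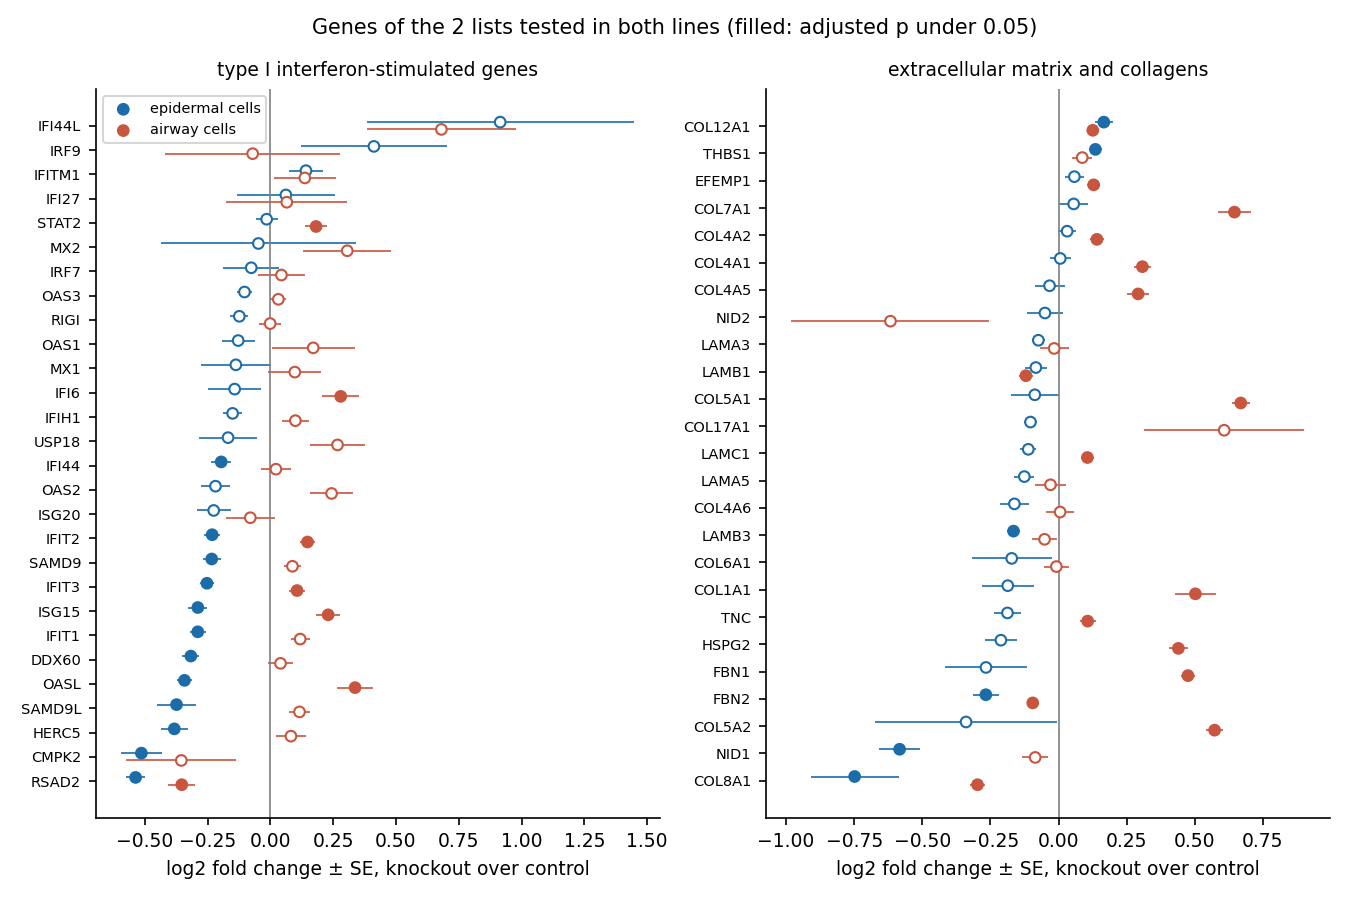
Log2 fold change (knockout over control, horizontal axis) with its SE for genes of the type I interferon and extracellular matrix lists tested in both lines; filled points have an adjusted p under 0.05. OASL lies at -0.34 in epidermal and 0.34 in airway cells, RSAD2 at -0.54 and -0.35, and COL5A1 at -0.09 and 0.67.

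The last comparison asks which genes changed with the knockout in both lines. COL4A4 (0.45 epidermal, 0.41 airway), the integrin chain ITGB8 (0.30, 0.19) and COL12A1 (0.17, 0.13) rose in both. FLI1 (-0.69, -0.48), IL24 (-0.45, -1.29), RSAD2 (-0.54, -0.35), ZNF185 (-0.39, -0.27), the adaptor SH3KBP1 (-0.28, -0.26), the endoplasmic reticulum chaperone HYOU1 (-0.19, -0.21), SLC37A2 (-0.19, -0.74) and PODXL (-0.18, -0.18) fell in both. More genes were called in opposite directions. Lower in epidermal and higher in airway knockouts were EEF1A2 (-0.81, 0.98), OASL (-0.34, 0.34), the proteoglycan SPOCK1 (-0.35, 0.31), the adhesion molecule L1CAM (-0.29, 0.41), APOL1 (-0.29, 0.25) and ECM1 (-0.23, 0.48). Higher in epidermal and lower in airway knockouts were the sodium leak channel NALCN (0.36, -0.28), TPCN1 (0.32, -0.25), the nucleolar NOP16 (0.26, -0.22) and CCDC86 (0.22, -0.32) and the activin antagonist FST (0.20, -0.43).

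Among the 14578 genes tested in both lines 3 rose in both (2.61 by chance for independent lists, adjusted p = 0.49, one-sided Fisher's exact test) and 15 fell in both (6.43 by chance, adjusted p = 0.0025). In opposite directions, 16 rose in epidermal and fell in airway cells (3.27 by chance, adjusted p = 3.5e-07) and 19 did the reverse (5.13 by chance, adjusted p = 1.5e-06). Fisher's test takes genes as independent and equally likely to be called, which was not tested, so these p-values may be too small. Thus 18 genes changed the same way and 35 in opposite directions; the second count was added after the data were seen, and 0 genes in either class changed at least 2-fold in both lines. The pair of counts was 5 and 8 without epidermal control 1, 5 and 6 without control 2, 7 and 7 without control 3, 49 and 81 without epidermal knockout 1 and 5 and 9 without epidermal knockout 3. Within the high carry-over level 17 genes changed the same way and 5 in opposite directions. With the level as a covariate the counts were 16 and 5, of which 9 and 4 were among the 18 and the 35. All 35 kept both signs there, and the median SE of called genes was 1.37 and 1.45 times as large in epidermal and airway cells. That fit reuses the libraries in which the 35 were called, so the kept signs are no separate support. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.026 and a Spearman correlation of -0.025.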

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

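The tests of chance splits and of gene length and GC content were planned, and the tests of carry-over, of the carry-over level and of the airway TMPRSS4 counts were chosen only after the result was seen. The results listed here stood out because the knockout effect differed between the lines in the interaction test of edgeR (Benjamini-Hochberg adjustment), or of camera for lists. Of 202 genes looked at, 112 did so (41 positive, 71 negative), as did 13 lists. The 202 were the genes named by the rule and expressed markers, many chosen because they were called, so their share follows from that choice. Among all genes tested 860 of 18091 were called. Values are epidermal minus airway log2 fold changes.

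Genes with a more negative effect in epidermal cells began with ZYG11A (-5.82), COL22A1 (-5.56), TMTC1 (-5.24), KLK5 (-5.07), PPP1R14C (-4.96), THBS2 (-2.47), EEF1A2 (-1.80), ACKR3 (-1.79), SMAD6 (-1.71), PDZK1IP1 (-1.67), CACNG4 (-1.29), EGR1 (-1.06), C1S (-1.01) and MUC1 (-0.96). Next came HMOX1 (-0.94), COL5A2 (-0.92), NEDD9 (-0.83), OLR1 (-0.83), EPPK1 (-0.82), VIM (-0.78), COL5A1 (-0.77), KRT17 (-0.76), FBN1 (-0.75), ECM1 (-0.72), L1CAM (-0.72), DSC3 (-0.72), COL1A1 (-0.70) and OASL (-0.69). They were followed by SPOCK1 (-0.67), HSPG2 (-0.66), SPARC (-0.64), DTNA (-0.60), APOL1 (-0.56), ISG15 (-0.53), CCL5 (-0.52), NID1 (-0.51), TGM1 (-0.50), SCNN1A (-0.47), TRAF1 (-0.46), C3 (-0.44), IFIT1 (-0.42) and INSIG1 (-0.41). After these came FN1 (-0.40), LIF (-0.39), IFIT2 (-0.39), P4HA2 (-0.39), KIF20A (-0.39), PFKFB4 (-0.38), TGFBR1 (-0.38), DDX60 (-0.37), HMGCS1 (-0.35), HLA-B (-0.34), F2R (-0.34), SOD2 (-0.34), ENO2 (-0.32) and ABCC3 (-0.32). Smaller negative differences were those of TGFBI (-0.30), JUP (-0.30), HSP90B1 (-0.25), ITGA5 (-0.24), PARP14 (-0.20), KIF11 (-0.19), FBN2 (-0.18), PDIA4 (-0.18), FTL (-0.16), DSG2 (-0.15) and NUSAP1 (-0.15). The smallest was that of KRT8 (-0.14).

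Genes with a more positive effect in epidermal cells began, from the smallest, with RPS3 (0.13), MYOF (0.14), PSAT1 (0.18), RPL23 (0.21), ATF4 (0.21), TXNRD1 (0.21), PARD3 (0.22), TRIB3 (0.23), ASAP1 (0.23), CD44 (0.23), DKK3 (0.25), ADM (0.28), PHLDA1 (0.30) and AEN (0.31). Larger differences were those of DUSP4 (0.32), SFRP1 (0.33), F3 (0.37), PLAT (0.39), DKK1 (0.44), NOP16 (0.47), FOSL1 (0.47), CCDC86 (0.53), SLC37A2 (0.55), TPCN1 (0.56), NALCN (0.62), FST (0.62) and COL13A1 (0.66). The largest were those of ANKRD1 (0.75), POLR1G (0.75), ARHGDIB (0.77), TGM2 (0.82), IL24 (0.83), DOCK4 (0.85), LPXN (0.95), NPAS2 (1.08), LAMP3 (1.08), COL27A1 (1.17), STEAP1 (1.24), FAT3 (1.96) and MMP1 (2.06).

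Among gene lists, mean differences were hyperproliferative and antimicrobial keratinocyte genes (-0.50), extracellular matrix and collagens (-0.33), cell junctions (-0.31), type I interferon-stimulated genes (-0.26), NF-kB feedback and TNF targets (-0.22), TGF-beta and BMP targets (-0.22), interferon-gamma response (-0.16), MHC class I presentation (-0.12), mitosis and cell cycle (-0.11), cholesterol synthesis (-0.10), AP-1 and immediate early genes (-0.011), cytosolic ribosomal proteins (0.090) and Hippo (YAP) targets (0.14). With an estimated correlation camera called 0 lists. For the AP-1 list the test pointed up although the mean was negative. ZYG11A, COL22A1, TMTC1, KLK5 and PPP1R14C, and PDZK1IP1 in airway cells, were near the floor in 1 line, so their fitted differences depend on the prior count. Expected carry-over was taken at the highest level of any library in the line, so its shares of the mean count are on the high side. In epidermal cells they were 48.3% for COL5A2, 36.2% for ZYG11A, 22.4% for SPARC, 12.4% for FBN1 and 6.62% for SMAD6. In airway cells they were 69.8% for COL22A1, 68.3% for DSC3, 25.2% for FST, 8.69% for JUP, 8.57% for PDZK1IP1 and 7.04% for COL27A1. For VIM (135%) and TMTC1 (150%) in epidermal and KLK5 (188%) and PPP1R14C (269%) in airway cells expected carry-over was more than was counted, so these differences are not read as effects of the knockout.

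Whether other splits of the libraries give as many calls was counted for each result. Within the epidermal line the real split gave 207 genes and 9 lists and the highest other split 0 genes and 3 lists. Within the airway line it gave 1443 genes and 12 lists against 0 genes and 9 lists. In each of these 4 counts 1 of the 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. Over both lines 100 of 200 splits were drawn. The real split gave 860 genes with a different effect, and 1 of 100 splits was as large (highest other 671). It gave 13 lists with a different effect, with 2 of 100 as large (highest other 13). These shares are under 0.05, but splits that kept the real airway groups, as they were or mirrored, and mixed the epidermal ones also gave many calls. For example, 1 such split gave 335 genes and another 13 lists. Both counts thus carry the changes within 1 line and do not decide whether the difference between the lines arose by chance. The real split gave 35 genes changed in opposite directions, with 1 of 100 as large (highest other 18), and 18 genes changed the same way, with 2 of 100 as large (highest other 35). The outcome for the counts of 35 and 18 was set by the splits within each line, where each other split called 0 genes, so they decide nothing on chance. The split with 671 genes, and with 35 and 18 exchanged, is the real one with the labels of 1 line mirrored.

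The first pattern is that 1443 genes were called in airway cells although TMPRSS4 lay at the floor there. Reads carried over from epidermal libraries are argued against as the whole cause, since 1439 genes were called with genes of at least 5% expected carry-over left out. A carry-over level, which may mark a sequencing pool, is argued against as the whole cause if it acts alike on both lines: in epidermal knockouts 2 and 3, the low ones, these genes should then have changed the other way by about as much, and the median ratio over 1366 genes was -0.0506 (quartiles -0.431 and 0.258). A level acting on the airway line alone stays open, since with the level as a covariate (468 genes called against 2 in the highest other split, and 327 against 83 in the epidermal line; median ratio of fold changes 0.9997, median SE 1.45 times as large) the comparison rests on airway control 3. For loss of a TMPRSS4 transcript, the 3 airway controls held 4 counts together where carry-over predicted 3.46 (95% counting interval 0.484 to 14.4). The 3 airway knockouts held 8 where 5.45 were predicted. No TMPRSS4 beyond carry-over was thus seen in either group. Loss of a transcript below that bound stays open, as the counts are too few to decide. Differences between knockout and control cells unrelated to TMPRSS4 were not tested.

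The second pattern is that traces of the other line's genes had 2 levels. Carry-over of reads between libraries predicted 8.91 TMPRSS4 counts over the 6 airway libraries and 12 were seen (95% counting interval 4.40 to 26.1), so the expected total lay inside the interval. Own expression of these genes changed by the knockout alone would set knockouts apart from controls. Yet airway control 3 (0.286%) lay above airway knockouts 1 and 2 (0.217 and 0.182%). Epidermal knockout 1 (0.294%) lay among the epidermal controls (0.281 to 0.309%). The knockout alone does not place these libraries, but they are only 1 per line, so a part played by it stays open. How the libraries were pooled or sequenced is not stated in the labels.

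The third pattern is that genes called in both lines went in opposite directions more often than in the same one. A carry-over level crossed with the knockout stays open as a source of the excess: with the level as a covariate 5 genes were called in opposite directions and 16 the same way, and in high carry-over libraries only 5 and 17. The 35 genes kept both signs with the covariate, in fits that rest on 1 library per line and under a larger SE, with median ratios of their fold changes of 0.908 in epidermal and 1.002 in airway cells. As these fits reuse the libraries in which the 35 were called, the kept signs decide nothing. A trend with gene length or GC content is argued against, since 35 of 35 genes kept at least 50% of both changes once the trends were removed, and length and GC content accounted for 0.625% and 0.373% of the variance in the epidermal and airway lines. The lines and their stimuli differ by design, and which of these may underlie the pattern was not tested.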

How the results depend on the processing

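The alternatives that used the carry-over level, left out genes with carry-over or halved the counts were chosen after the data were seen, and the others were planned. The TMPRSS4 level in epidermal cells kept its direction and its call under each alternative run, from -1.47 to -1.17 on the log2 scale.

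For genes changed by knockout, epidermal cells, the count of 207 became 19 with a log2 fold change of at least 1, 464 with no filter on low counts, 341 with all 12 libraries in a joint fit, 327 with the carry-over level as a covariate (83 in the highest other split) and 325 in high carry-over libraries only. Leaving out 1 library gave 48 to 601. For genes changed by knockout, airway cells, the count of 1443 became 66 with the fold limit, 468 with the covariate and 402 in high carry-over libraries only, and leaving out 1 library gave 866 to 1141. For knockout effect differs between cell lines, the count of 860 became 91 with the fold limit, 333 with the covariate and 364 in high carry-over libraries only, and leaving out 1 library gave 554 to 1126. The fold limit asks more by construction, and for the other changes the cause was not tested.

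For genes changed the same way in both cell lines, the count of 18 became 0 with the fold limit in both lines, 43 with no filter, 36 in the joint fit, 16 with the covariate and 17 in high carry-over libraries only, and leaving out 1 library gave 5 to 49. For genes changed in opposite directions in the 2 cell lines, the count of 35 became 0 with the fold limit, 74 with no filter, 5 with the covariate and 5 in high carry-over libraries only, both below the counts for the same way, and leaving out 1 library gave 6 to 81. The correlation of knockout fold changes between cell lines, 0.026, turned negative with no filter (-0.00098) and with the stricter filter of 5 CPM in 3 libraries (-0.049), and was 0.0061 in the joint fit, 0.053 with the covariate, 0.013 in high carry-over libraries only and 0.00030 to 0.040 with 1 library left out. The cause was not tested.

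For gene lists past the threshold, epidermal cells, the count of 9 became 0 with an estimated correlation and 5 in high carry-over libraries only. For gene lists past the threshold, airway cells, 12 became 0 with an estimated correlation, 7 with the covariate and 4 in high carry-over libraries only. For gene lists whose knockout effect differs between cell lines, 13 became 0, 7 and 6. The mean of the list interferon-gamma response, epidermal, -0.07, was 0.093 in high carry-over libraries only and -0.073 to 0.064 with 1 library left out. Fits that left libraries out reran the filter, so list members could change and these means may cover different genes. The list interferon-gamma response, int (the difference between lines), -0.16, was 0.030 with the covariate, 0.18 in high carry-over libraries only and -0.18 to 0.023 with 1 library left out. The list AP-1 and immediate early genes, airway, -0.07, was 0.0020 in high carry-over libraries only and -0.082 to -0.0040 with 1 library left out, and the list AP-1 and immediate early genes, int, -0.01, was -0.030 to 0.0012 with 1 library left out. The cause was not tested.

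Named genes kept their direction under each alternative. The alternatives reuse the libraries that chose these genes. For the largest rises and falls the rule also required knockouts and controls not to overlap. Kept directions were thus largely set in advance and are no separate support. Of their calls, 163 were kept and 21 lost in the joint fit, 128 and 80 with the covariate, 125 and 83 in high carry-over libraries only, 205 and 3 with DESeq2's Wald test, 207 and 1 with DESeq2's size factors, 205 and 3 with no filter, 200 and 2 with the stricter filter, 199 and 0 with genes with carry-over left out and 203 and 4 with counts halved; over fits with 1 library left out, 1112 were kept and 280 lost. Replicate numbers were not taken as pairs, since correlations of residuals of controls and knockouts with the same number were under a limit of 0.1. They were -0.024, 0.0089 and 0.0023 in epidermal and 0.0024, 0.076 and 0.040 in airway cells. With different numbers they ran from -0.023 to 0.021 in epidermal and from -0.086 to 0.048 in airway cells. Some pairing in the airway line stays open, as more genes were called there with the block. With the number as a block the counts were 181, 1898 and 953 genes in the epidermal, airway and interaction tests, and 198 named calls were kept and 10 lost. Depth limited genes near the floor of 3 counts per library, TMPRSS4 in airway cells among them.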
